A study of Mus musculus with 10 samples.

How the data were processed

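Hi-C measures how often pairs of DNA segments lie close together in the nucleus: chromatin is fixed, cut, ligated, and sequenced from both ends of the joined fragments. Here it was applied to mouse tail fibroblasts of a mixed C57/B6 and 129sv background before, and on days 2, 4, 6 and 14 after, lentiviral expression of Foxa3, Gata4 and Hnf1a, the factors used to turn fibroblasts into hepatocyte-like cells. The labels list 10 samples, 2 per time point. The deposited maps pool both samples of a time point, so 5 maps were analysed, with no replicate to compare at any time point.

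Per the labels, the authors cut the chromatin with DpnII and marked the ends with biotin. Reads were aligned with Bowtie 1.1.1 to the mm10 mouse genome, per the submitters' processing notes. The pairing, filtering and binning steps are not given in the sources used here. Each deposited file holds contact counts: whole numbers of contacts between pairs of 40 kb bins of one chromosome, not normalized. The lowest count listed is 11 in every map, so a pair that is not listed had 10 or fewer contacts. This minimum removes most distant pairs and removes more of them from shallower maps.

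The chromosome names in the files did not match mm10. The last bin of each name fitted the length of another chromosome, and only 1 of the 20 names carried its own length. Names were reassigned by length and checked by regressing the log of same-bin contacts on the density of DpnII sites, GC content and repeat content of each mm10 chromosome. The matched pairings gave R² between 0.08 and 0.557, with a median of 0.337. All other pairings had a median of 0.009 and a highest value of 0.088. All coordinates given are mm10 after this reassignment, counted from 1, and genes were placed by their annotated transcription start.

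Listed contacts numbered 375538511 at day 0, 210768773 at day 2, 260939900 at day 4, 246405954 at day 6 and 293948104 at day 14. Because the count minimum acts differently at different depths, every map was thinned at random to the 72628508 contacts that day 2 had at 40 to 400 kb on autosomes other than 15, and the minimum of 11 was applied again. Day 0 kept 54.7% of its contacts, day 4 kept 84.7%, day 6 kept 87.1% and day 14 kept 77.0%. Chromosome 15 was left out of the depth because a stretch of it had very different coverage between maps. The plan had taken full depth as the main setting for several measures, and the order was turned after the count minimum was found, so full depth is the alternative throughout.

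Insulation was scored at each 40 kb bin as the log2 of the mean contacts between the 10 bins on its left and the 10 bins on its right (400 kb) over the chromosome mean. A higher score means more contacts across the bin, and a low score marks a boundary. Unlisted pairs were set to 5. Bins that were empty, or among the 2% of lowest coverage of their chromosome, in any of the 5 maps were removed, which kept 57513 of 61578 autosomal bins. The band of contacts used was balanced by iterative correction in 30 rounds. The plan did not say whether to balance for this measure. Balancing was chosen after coverage was seen to follow GC content and before any gene's value was seen, and unbalanced scores are an alternative. In all, 54025 autosomal bins had a score at every time point. Borders were local minima with a rise of at least 0.2 on both sides within 10 bins, and were counted as shared when within 1 bin. Domains of 200 kb to 3 Mb were taken between neighbouring day 0 borders, and 3221 were measured. The local share is the percent of a bin's listed contacts, same-bin contacts left out, that join it to bins 80 to 400 kb away. Changes of the local share at genes are given less the change of the median gene bin on that day.

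Day 0 was divided at random into equal parts, and the 99th percentile of the absolute difference between those parts set the counting-error bound: 0.088 for the insulation score, 4.07 percentage points for the local share and 1.5 points for contacts inside a single domain. These bounds and all intervals cover counting error only, and PCR copies would make them too narrow. Changes beyond the bound are called higher or lower. Tests across replicates could not be made, so no p-values are given. Genes were grouped in 14 lists, and members sharing a bin were counted once. A list's median change was placed among 10000 random lists of the same size, matched on the day 0 value, as a description of these maps. The 14 lists were hepatocyte plasma proteins, hepatocyte metabolism and transport, hepatic transcription factors, epithelial junctions and keratins, fibroblast matrix and cytoskeleton, mesenchymal transcription factors, Hox genes, intestine and biliary genes, housekeeping genes, and markers of neuronal, immune, muscle, endothelial and keratinocyte cells. Of 236 genes in the lists, 4 are on X and were left out, and 217 had an insulation score.

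The lists, the measures and the rule for naming genes were fixed before the data were examined. That rule named 14 genes in every case, then the genes of the lists whose compartment value changed most and those whose insulation score changed most by day 14. Compartments could not be read from these maps. The principal component that followed gene density best among the first 3 had a median absolute correlation with it of 0.15 to 0.2 over chromosomes, against 0.18 to 0.22 with the gene density of the same chromosome in reverse order. Compartment values, switches and strength are therefore not reported. In the rule, the 10 genes highest and the 10 lowest in insulation change took the place of the compartment genes, the 5 highest and 5 lowest in local share change took the next place, and the regions are the 5 longest runs of changed 40 kb bins in each direction. The planned decay slope from 0.4 to 4 Mb was replaced by 80 to 800 kb, where most pairs are listed.

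The steps were tested on simulated data made from the day 0 map. When contacts across a bin were reduced to 0.7 of their number, 100% of 100 changed bins passed the insulation bound, and 99% passed when they were reduced to 0.85. Of 42405 unchanged bins, 1.1% passed, but the bound was set on the same random parts, so this share was largely fixed in advance. For the local share, 100% were recovered at 0.7 and 48% at 0.85. Of 13704 unchanged bins 1.0% were past the bound, which was again set on the same parts. Among 200 unchanged lists of 20 bins, 3.0% fell outside the middle 95% of random lists. Alternatives covered windows of 200 and 800 kb, full depth, the border rise and tolerance, the fill for unlisted pairs, balancing, chromosomes 15 and X, domains from day 14, the slope range, another thinning, GC matching and 1 bin per 1 Mb of a list. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.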

Results

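Chromatin contacts were mapped by Hi-C in mouse tail fibroblasts at day 0 and at 2, 4, 6 and 14 days after lentiviral expression of Foxa3, Gata4 and Hnf1a, transcription factors of the liver. The series follows chromatin structure over the time course of conversion to hepatocyte-like cells. Each time point is represented by 1 map that pools 2 samples, so no difference between days has a replicate check, and errors given are counting errors. The maps held 2807018, 1965785, 1870775, 1783496 and 2107896 listed bin pairs from day 0 to day 14, all within chromosomes and with 11 or more contacts each. Contacts within a 40 kb bin made up 44.3% of the total at day 0, 47.8% at day 2, 53.1% at day 4, 51.9% at day 6 and 51.8% at day 14. These totals and percentages, and the coverage of chromosomes and their stretches, were taken at full depth, and the other values come from maps of matched depth unless stated.

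How the surroundings of liver and fibroblast genes changed was addressed with the insulation score at each gene's transcription start, where a higher score means more contacts across the bin. The highest gain at a listed gene was at Tdo2, which encodes the liver enzyme that starts tryptophan breakdown (chromosome 3, 81957090 to 81976202). Its score was -1.40 at day 0, rose by 0.48 at days 2 and 4, 0.77 at day 6 and 0.92 at day 14, and ranked 16th among 12908 gene bins. The minimum at day 0 lay in the adjacent bin from 81920001, which went from -1.662 to -0.695 at day 14, so the gain is not particular to Tdo2. Foxa2, a pioneer factor of endoderm (chromosome 2, 148042877 to 148046969), rose by 0.28, 0.22, 0.43 and 0.58 on the successive days. At Ttr, which encodes the plasma carrier transthyretin (chromosome 18, 20665280 to 20674321), the gains were 0.25, 0.13, 0.26 and 0.45. In the other direction, Col1a1, which encodes the main chain of type I collagen (chromosome 11, 94936224 to 94953042), fell by 0.21 at day 2, 0.49 at day 4, 0.55 at day 6 and 0.47 at day 14, from a score of 0.19 at day 0. Changes at single genes, unlike those of lists, were not matched on the day 0 score. Foxa2 (-0.90) and Ttr (-0.60) also had low scores at day 0. Bins of day 0 borders, which have low scores, rose on average from -0.744 to -0.654 at day 14, and this shared part was not removed.

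The endogenous loci of all 3 introduced factors had higher scores at day 14 than at day 0. Foxa3, in a border bin at all time points, had a change of -0.22 at day 2, 0.01 at day 4, 0.12 at day 6 and 0.28 at day 14. Gata4 reached 0.10 and Hnf1a 0.15 at day 14, and their earlier changes lay within the bound of 0.088. Among liver genes named in advance, Serpina1a, which encodes the main blood protease inhibitor, was higher on every day (0.25, 0.19, 0.20 and 0.32), as was its neighbour Serpina1b, with 0.36 at day 14. Both lie in a cluster of near-identical copies, where reads are hard to place, and their contact counts were low. Hnf4a, a central regulator of hepatocytes, was higher at days 2, 4 and 14 (0.24, 0.20 and 0.25) with 0.01 at day 6. Apoa1, which encodes the main protein of high-density lipoprotein, was at 0.14 at day 14. Afp, the fetal counterpart of albumin, was at 0.10, and Alb, the albumin gene, was within the bound at 0.06. The bile acid and organic anion carriers Slc10a1 and Slco1b2 gained 0.39 and 0.56 by day 14, after -0.06 and -0.45 at day 4.

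Fibroblast and mesenchymal genes moved in both directions. Thy1, a surface marker of fibroblasts, was lower on every day and by -0.38 at day 14. Eln, which encodes elastin, stood at -0.35 and Lox, which encodes the enzyme that crosslinks collagen and elastin, at -0.34 on that day, with lower values at days 2, 4 and 6 as well. Col6a3 (-0.25) and Twist2 (-0.23) were also lower at day 14. The mesenchymal factors Twist1 and Snai2 were higher on all 4 days. Twist1 went from 0.29 at day 2 to 0.60 at day 14, Snai2 from 0.69 at day 2 to 0.46 at day 14, and Foxc2, which shares its bin with Foxf1, was at 0.45 at day 14. Postn, which encodes periostin, was at 0.37. Values of 0.06 at Prrx1 and -0.02 at Col1a2 were within the bound. Genes of other cell types changed too: Cd3e of T cells (0.43), Dsg3 of keratinocytes (0.42) and Cdh5 of endothelium (0.23) were higher at day 14. The bins of Dsg3 (from 20480001) and Ttr (from 20640001) lie on chromosome 18 within 1 window of 400 kb. The bin from 20600001 between them went from -0.977 at day 0 to -0.383 at day 14, so the 2 gains are not separate changes. Lower at day 14 were Cx3cr1 of macrophages (-0.43), the endothelial factor Erg (-0.38), the neuronal glutamate carrier Slc17a6 (-0.31) and Tbp of the basal transcription machinery (-0.25). The bin of Cx3cr1 (from 120040001) lies on chromosome 9 within 1 window of 400 kb of bins that fell more. That of Gorasp1 and Ttc21a (from 119920001) changed by -0.81, so the fall is not particular to Cx3cr1. Slc17a6 lies on chromosome 7 between 46 and 68 Mb, where same-bin contacts were raised at days 4 and 14 (log2 0.50 and 0.42). Its score changed by -0.03, -0.23 and -0.09 at days 2, 4 and 6, so its change cannot be told apart from that coverage difference. With a window of 200 kb the changes at Gata4 (0.09), Hnf1a (0.07), Cx3cr1 (-0.09) and Twist2 (-0.03) were within that window's bound. With 800 kb that at Hnf4a (0.05) was within the bound and Apoa1 was lower (-0.14). Afp at full depth (0.07) and with another thinning (0.08), and Col6a3 without balancing (-0.04), were within the bound of the setting. With unlisted pairs at 0, Gata4 (0.11) and Afp (0.11) were within that setting's bound as well.

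**Figure D1:**
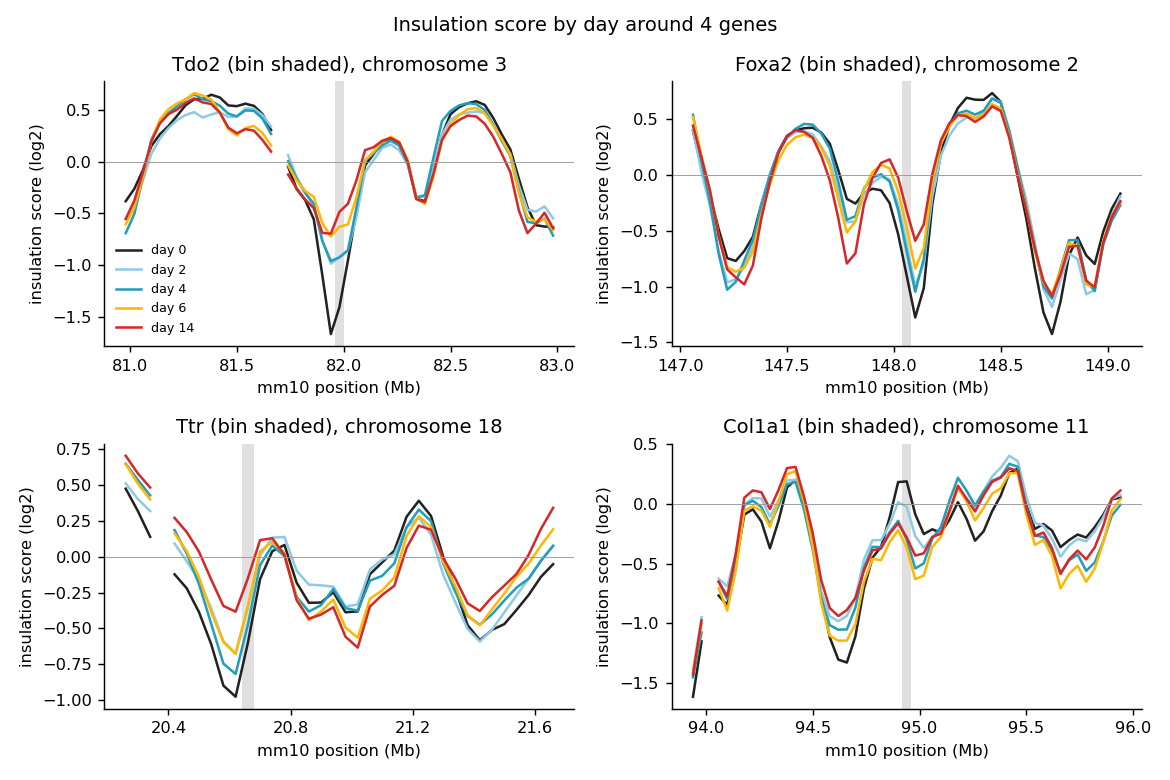
Insulation score (log2, vertical axis) in 40 kb bins within 1 Mb of Tdo2, Foxa2, Ttr and Col1a1 (horizontal axis, mm10 position in Mb), with 1 line per time point. At the gene's bin the score rises from -1.40 to -0.49 for Tdo2 between day 0 and day 14 and falls from 0.19 to -0.28 for Col1a1.

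Across gene groups, hepatocyte plasma protein genes had the largest upward median at day 14 in the main setting. Of their 21 bins, 14 were higher and 2 lower, and the median change was 0.118 ± 0.015 (95% counting error), at percentile 98.8 among matched random lists. Immune genes had 0.108 ± 0.009, so the 2 intervals overlap. Plasma protein members that rose included Trf (0.19), Rbp4 (0.16) and Kng1 (0.16), which encode carriers of iron and retinol and a kininogen. Ambp (-0.19) and Vtn (-0.09) were lower. On days 2, 4 and 6 the list's median was 0.087, 0.033 and 0.042, at percentiles 86.8, 63.4 and 96.7. The day 14 median was 0.301 without balancing, and its percentile was 94.2 at full depth, 96.2 with a window of 800 kb, 97.2 with unlisted pairs at 10 and 97.4 with 1 bin per 1 Mb. In all, 3 of the 56 insulation percentiles (14 lists on 4 days) lay outside the middle 95%, against 2.8 for random lists. The gene background itself moved, with 33.7% of gene bins higher and 19.6% lower at day 14.

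The medians of the other liver lists lay within the middle 95% of random lists at day 14. Hepatic transcription factors had a median of 0.056 with 8 bins higher and 1 lower of 18 (percentile 83.1, range 12.0 to 93.5), and the lower member was Nr1i2 (-0.13), a sensor of foreign compounds. Genes of hepatocyte metabolism and transport had a median of -0.006, although 9 of 21 bins were higher, among them Fbp1 of gluconeogenesis (0.35) and Cyp2e1 of drug oxidation (0.22), and 2 were lower (percentile 6.2, with a range of 5.5 to 94.5 over the alternatives). Fibroblast matrix and cytoskeleton genes had 4 bins higher and 6 lower of 21, with a median of -0.03 at percentile 6.9 (1.5 with a window of 200 kb, 0.9 without balancing and 58.0 with 800 kb), and their day 2 median of -0.025 lay at percentile 2.2, with a range of 0.4 to 23.1. Mesenchymal transcription factors had 6 higher and 3 lower of 19 at day 14 (median -0.003, percentile 36.2). Their day 2 median of 0.078 was at percentile 98.1, and at 42.7 without balancing. Epithelial junctions and keratins had 3 higher and 2 lower of 15 (-0.032, percentile 7.9), and Hox genes, which set body position, 0 higher and 2 lower of 12 (0.009, percentile 22.0). Intestine and biliary genes had 5 higher and 2 lower of 12 (0.062, percentile 85.0), and housekeeping genes 5 higher and 1 lower of 12 (0.064, percentile 44.1).

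Markers of other cell types were measured in the same way. Immune genes had 9 bins higher and 2 lower of 13 at day 14, with a median of 0.108 at percentile 95.4. This percentile ranged from 64.8 without balancing to 98.9 with another thinning, and was above that of plasma proteins at full depth (97.3 against 94.2), with a window of 800 kb (98.2 against 96.2), with another thinning (98.9 against 98.0) and with unlisted pairs at 10 (97.6 against 97.2). Csf1r of macrophages (0.19), Cd19 of B cells (0.16) and Ikzf1 of lymphocytes (0.12) were among the higher ones. Neuronal genes had 5 higher and 3 lower of 13 (0.008, percentile 66.2) and endothelial genes 3 higher and 2 lower of 11 (0.016, percentile 53.0). Muscle genes had 1 higher and 0 lower of 10 (-0.008, percentile 33.1), and keratinocyte genes 1 higher and 0 lower of 8 (0.018, percentile 57.2). Chromosome X held 1.38 times its day 0 share of contacts at day 4 and 1.39 times at day 14, against 0.87 at day 2 and 0.96 at day 6, so the maps of days 4 and 14 stood apart on this measure from the others beside every list.

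The share of contacts at 80 to 400 kb was lower at fibroblast matrix and cytoskeleton genes than at matched random lists on each day after day 0. It is a share of listed contacts, so more contacts at other distances lower it as well. The local share of their 22 bins, relative to the median gene bin, had a median change of -2.9 points at day 2, -2.69 at day 4, -2.87 at day 6 and -4.06 ± 0.57 at day 14. At day 14, 11 bins were lower and 1 was higher. Lower members were Col5a2 (-10.0), which encodes a fibrillar collagen, Postn (-8.1), Fn1 for fibronectin (-7.9), Eln (-7.9), Thy1 (-7.9), Tagln (-5.8) and Col5a1 (-5.4). The higher one was Col1a1 at 7.3. The percentiles among random lists were 0.1, 0.2, 0.0 and 0.0. These 4 changes share the day 0 map, and with a window of 800 kb the medians were -2.03, -0.89, -0.19 and -1.09, at percentiles 0.9, 13.3, 41.9 and 8.9. With that window Eln (-3.7), Thy1 (-3.1) and Postn (1.3) were within the bound, as was Col1a1 with 200 kb (2.4).

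Hox genes had a median change in local share of -2.72 points at day 14 (percentile 0.4), with 0 higher and 4 lower of 12 bins. That percentile was 4.9 with 1 bin per 1 Mb, 4.1 with a window of 200 kb and 3.9 with another thinning. Their medians were -1.05, -2.68 and -1.88 on days 2, 4 and 6, and members of a cluster are neighbours. Muscle genes had a median of -2.72 at day 4 (percentile 0.8) and -2.07 at day 14 (percentile 2.8, with 0 higher and 2 lower of 11). Their day 4 percentile was 2.6 with GC matching, 3.8 at full depth, 10.8 with another thinning and 12.0 with a window of 800 kb. With a window of 200 kb it was 0.3 at day 4, 1.6 at day 6 and 0.0 at day 14, where the median of -3.89 lay below the -3.61 of the fibroblast matrix list in the same window. Among single genes of the 14 lists at day 14, Serpina1b (20.5) and Serpina1a (18.4) had the highest gains, with the limits of their cluster. Foxa2 (10.4), Cdh5 (10.1) and Aldob of fructose metabolism (9.2) followed. Afp gained 7.6. The lowest were Cdh1, the epithelial cadherin (-10.4), Col5a2, Twist2 (-8.6) and Myf5, a regulator of muscle (-8.3). For the other lists at day 14 the median and percentile were 0.28 and 68.0 for plasma proteins, 0.23 and 25.2 (range 5.6 to 93.8) for metabolism and transport, and -0.44 and 36.8 (range 7.3 to 96.5) for hepatic transcription factors. They were -1.08 and 6.2 for epithelial genes, -1.61 and 5.0 for mesenchymal factors (0.3 at full depth, 2.4 with another thinning and 27.7 with a window of 200 kb), 1.34 and 91.6 for intestine and biliary genes, and -1.77 and 5.6 for housekeeping genes. Markers of neuronal cells had -1.06 and 24.9, immune -0.12 and 47.3, endothelial -0.4 and 22.2, and keratinocyte -0.26 and 29.4. In the local share, 8 of 56 percentiles lay outside the middle 95%.

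**Figure D2:**
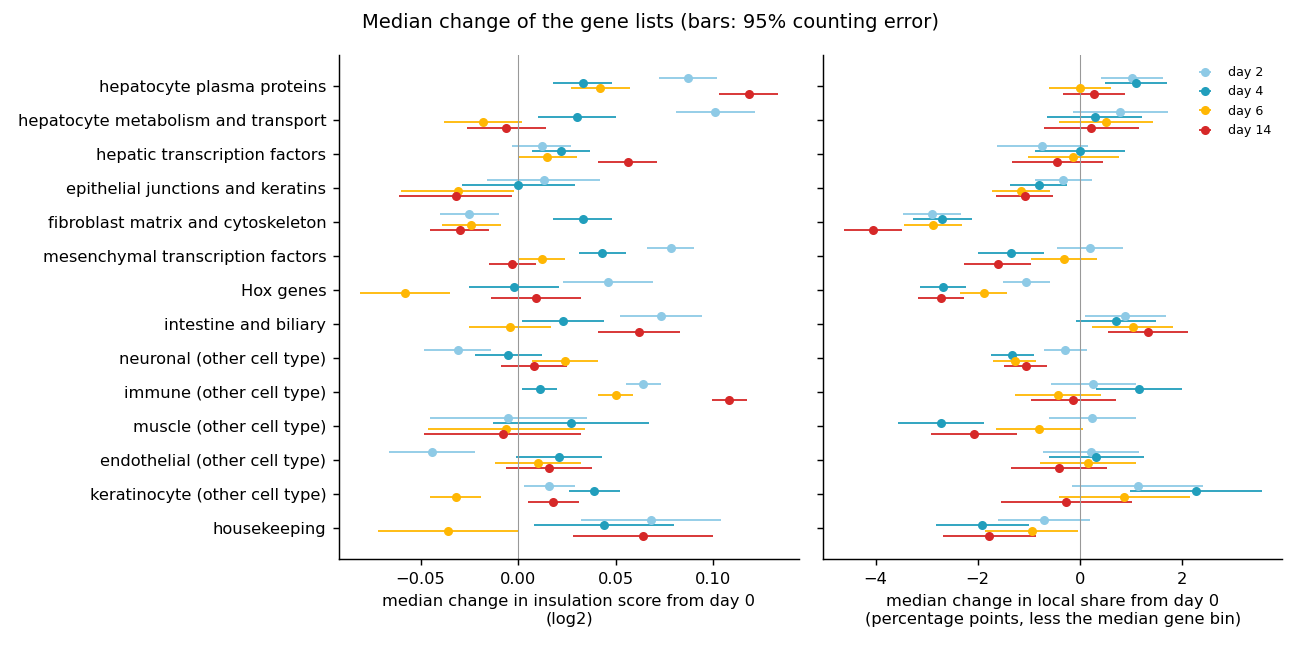
Median change from day 0 of 14 gene lists on days 2, 4, 6 and 14, in insulation score (log2) and in local share (percentage points less the median gene bin), with bars for the 95% counting error. Fibroblast matrix and cytoskeleton genes lie below 0 in local share on all 4 days, reaching -4.06 at day 14, and plasma protein genes reach 0.118 in insulation score.

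Changed bins lay next to each other in runs. The longest run of adjacent bins with higher scores at day 14 spanned 1200 kb on chromosome 10 (126920001 to 128120000), which holds Cdk4, Gli1, Stat6 and Lrp1, with mean changes of 0.14, 0.15, 0.08 and 0.19 from day 2 to day 14. The run on chromosome 5 from 75040001 to 75920000, over the receptor genes Pdgfra and Kit, gained 0.02, 0.13, 0.19 and 0.38. Runs of 800 kb were found on chromosome 6 (42560001 to 43360000, olfactory receptors and Tpk1; 0.32 at day 14), chromosome 3 (87440001 to 88240000, with Nes and Ntrk1; 0.25) and chromosome 14 (57440001 to 58240000, with Fgf9 and Lats2; 0.19). Lower scores ran over 960 kb of chromosome 15 (94960001 to 95920000, with Ano6 and Nell2), with -0.08, -0.11, -0.13 and -0.24. On chromosome 5 from 120040001 to 120960000, over the antiviral Oas genes and the liver enzyme gene Sds, the run had -0.06 at days 2 and 4, -0.28 at day 6 and -0.36 at day 14. Other lower runs lay on chromosome 2 (158720001 to 159600000, with Dhx35 and Ppp1r16b; -0.24), chromosome 3 (46080001 to 46880000, with Pabpc4l; -0.18) and chromosome 15 (67400001 to 68120000, with Zfat; -0.17). Scores of neighbouring bins share most of their contacts, so a change at 1 place extends over a run by construction. Between random parts of day 0 the longest runs were 200 kb higher and 160 kb lower. The bound was set on those same parts, so few of their bins could pass it, and these lengths do not show what to expect at day 14.

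Genome-wide, the insulation profile kept most of its shape. Its correlation with day 0 across 54025 bins, which are not independent replicates, was 0.968 at day 2, 0.961 at day 4, 0.965 at day 6 and 0.945 at day 14, and 0.983 between days 6 and 14. Equal random parts of day 0 gave 0.998. At day 14, 13740 bins (25.4%) were higher and 12813 (23.7%) lower past the bound, and 703 changed by more than 0.5, against 132 at day 2, 242 at day 4 and 233 at day 6. Bins past the bound at day 2 numbered 12035 higher and 9794 lower, at day 4 12232 and 12142, and at day 6 10680 and 11312. Without balancing, day 2 had 21179 higher and 19771 lower.

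Domain borders numbered 3603, 3554, 3774, 3761 and 3734 from day 0 to day 14. Of the day 0 borders, 87.8% were found at day 2, 88.5% at day 4, 89.5% at day 6 and 87.3% at day 14, against 96.1% between random parts of day 0. Borders not seen at day 0 numbered 392, 586, 535 and 590. Near named genes, the border in the bin of Slco1b2 at day 0 had its nearest counterpart 160 kb away at day 14, and that at Foxc2 280 kb away. The nearest border to Eln moved from 280 kb to the gene's own bin. Day 0 borders had a mean score of -0.744 at day 0 and -0.654 at day 14, and borders chosen at day 14 had -0.701 and -0.678. Scores of all bins had an SD of 0.49 at day 0 and 0.448 at day 14.

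Contacts inside domains made up a median of 65.2% of the listed contacts of a domain's bins at day 0, over 3221 domains (SD 13.3 over domains). The median change was -3.67 points at day 2, 1.19 at day 4, 2.89 at day 6 and -0.24 at day 14. At day 2, 2794 domains moved down and 427 up, at day 4 1098 and 2123, at day 6 285 and 2936, and at day 14 1734 and 1487. At full depth the changes were -0.21, 3.7, 5.83 and 1.86, so day 14 had the opposite sign.

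By share, listed contacts shifted towards shorter distances at days 4, 6 and 14, but the slope of contacts against distance was steeper than at day 0 at day 6 alone. Of the contacts between different autosomal bins, 46.34% spanned 200 kb to 2 Mb at day 0 (95% Wilson interval 46.328 to 46.347), 46.82% at day 2, 41.86% at day 4, 42.53% at day 6 and 45.03% at day 14. The share was higher than at day 0 on 19 of 19 autosomes at day 2, lower on 19 at days 4 and 6, and lower on 18 at day 14. At full depth it was 46.75% at day 0 and 46.82% at day 2, so most of the day 2 rise was absent there. The full-depth values at days 4, 6 and 14 were 42.43%, 42.99% and 45.76%. Pairs under 200 kb had 51.74%, 50.46%, 56.79%, 56.25% and 53.63%. The slope of median contacts against distance from 80 to 800 kb on log axes was -1.14 at day 0 (SD 0.06 over chromosomes), -1.07 at day 2, -1.14 at day 4, -1.20 at day 6 and -1.11 at day 14. Between 400 and 800 kb the day 4 slope was 0.08 above day 0, and the shares contain listed pairs alone, so distant contacts are undercounted.

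**Figure D3:**
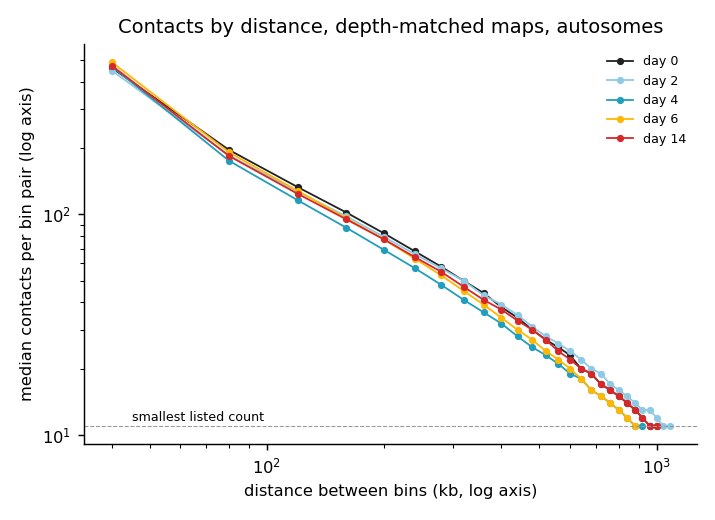
Median contacts per bin pair (vertical log axis) against distance in kb (horizontal log axis) on autosomes in maps of matched depth, 1 line per time point. The day 6 line is the steepest, with a slope of -1.20, and the day 2 line the flattest, with -1.07.

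Coverage per chromosome was compared as a check on copy number and on mixed cells. Chromosome 15 held 5.04% of all contacts at day 0, 5.75% at day 2, 4.52% at day 4, 5.24% at day 6 and 5.33% at day 14. Chromosome X held 2.6%, 2.26%, 3.6%, 2.49% and 3.61%. The other 18 autosomes stayed between 0.91 and 1.14 times their day 0 share. Within chromosome 15, a stretch of 2.64 Mb from 60800001 to 63440000, which holds the proto-oncogene Myc with Fam84b and A1bg, had same-bin contacts at 8.83 times the autosomal median at day 2 (SD 2.38 over 66 bins). The level was 1.66 at day 0, 1.37 at day 4, 3.43 at day 6 and 5.67 at day 14, while its flanks stayed between 1.09 and 1.19.

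**Figure D4:**
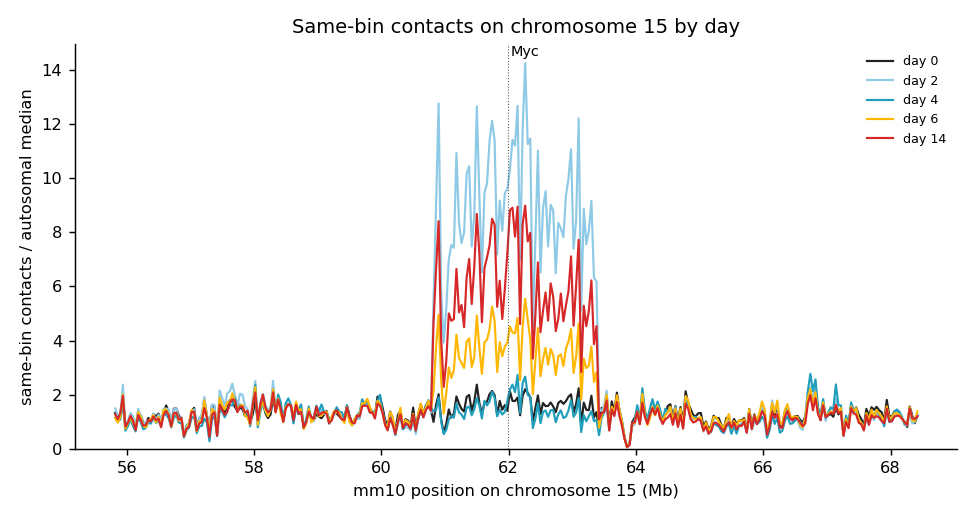
Same-bin contacts over the autosomal median (vertical axis) in 40 kb bins of chromosome 15 around Myc (horizontal axis, mm10 position in Mb), 1 line per time point. The stretch holding Myc stands at 8.83 at day 2 and 5.67 at day 14, against 1.66 at day 0 and 1.37 at day 4.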

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

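The tests in this part were chosen after the coverage differences were seen, except that the test of joined ends was written before its own value was known. The values stand out because same-bin coverage, which the comparisons of insulation and distance leave out, and the contacts between the ends of a stretch lay above day 0. The end-to-end contacts do enter the shares by distance, where leaving out chromosome 15 changed the 2 to 10 Mb share at day 14 from 1.32% to 1.27%.

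Same-bin contacts of the 2.64 Mb around Myc on chromosome 15 were 8.83 times the autosomal median at day 2, 3.43 at day 6 and 5.67 at day 14, against 1.66 at day 0. Among the bin pairs that join the ends of the stretch, the highest count of a single pair, at matched depth, was 1416, 378 and 1070 on those days. It was 72 at day 0 and 93 at day 4. Reads placed from a repeated sequence would raise every map alike, but the factor over the flanks differed 6.87 times between maps, and a steady rise with days under the 3 factors is argued against by a day 4 factor that was 0.15 of day 2. Extra copies with their ends joined, in part of the cells, may account for it. Inside the stretch at day 2, pairs nearly as far apart as its length had 1.69 times the contacts of pairs separated by about 0.5 of it, where distance alone would give fewer. At days 0 and 4 that ratio was 1.03, which is also not fewer, so these maps may hold a small share of such copies too (1.4 and 1.18 times the flanks). The test took the place of an earlier one, the highest end-to-end count over the median of inside pairs nearly as far apart. Its value of 4.0, a maximum over a median, lay between its bounds. Whether copies lie in tandem or apart from the chromosome stays open.

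Same-bin contacts on chromosome X were 0.673 of the autosomal median at day 4 and 0.632 at day 14, above 0.442 at day 0, 0.402 at day 2 and 0.422 at day 6. GC content is argued against, since 0.78 (log2) was left at day 4 after its trend was removed, and so is a rise with days, since day 6 was at 0.63 of day 4. Cells of different origin in different maps, such as cultures with other shares of male and female cells, could account for it: 29 of 2379 autosomal segments of 1 Mb were raised at both days 4 and 14 and 3 at both days 2 and 6. This evidence is limited, since 17 of the 29 lie on chromosome 7 and 2 of the 3 lie in the stretch around Myc, which leaves 12 against 1. On chromosome 7 the median log2 ratio to day 0 from 46 to 68 Mb was 0.50 at day 4 and 0.42 at day 14, against -0.04 and -0.01 at days 2 and 6. That range runs from the first to the last of the 17 segments, so its high medians at days 4 and 14 follow in part from how it was picked. Gained copies of X and of that part of chromosome 7, strain differences between cultures, and a true change with the 3 factors at days 4 and 14 alone were not tested apart.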

How the results depend on the processing

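The alternatives of balancing, the fill for unlisted pairs, chromosome 15, GC matching, 1 bin per 1 Mb, another thinning and the 400 to 800 kb slope were chosen after seeing the data. No paired analysis was possible because the deposited maps pool the replicates of each time point, and for the same reason no replicate could be left out. The compartment alternatives, and the slope to 10 Mb, were not run as results because the compartment signal was void and distant pairs are unlisted. Over 18 settings, 1386 of 1721 alternative values were classed as the same, 332 as moved without a change of sign at a called value, and 3 called gene values reversed. List medians, border percentages and gene values had to stay within their error, and counts and ratios within a fixed margin. For shares by distance and slopes the margin was the SD over chromosomes, and for inside-domain medians the 1.5-point bound of a single domain. These margins can exceed the change itself, so being classed as the same says little there. The share at 200 kb to 2 Mb counted as the same at full depth, with 46.75% at day 0 and 46.82% at day 2 (SD 1.53 over chromosomes at day 2). Percentiles only had to stay inside or outside the middle 95% on the same side. The insulation percentile of metabolism and transport at day 14 thus counted as the same at 6.2 and, with 800 kb, at 94.5. Of 345 alternative values of genes called in the main setting, 21 were no longer past the bound. For none of the following changes was the cause tested, except where named.

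With a window of 200 kb, the bins counted as changed fell to 7366 higher and 5749 lower at day 2, 7905 lower at day 4, 6916 and 6967 at day 6, and 8215 lower at day 14. Without balancing they were 21179 and 19771 at day 2, 22106 and 22639 at day 4, and 17575 higher at day 6. Day 0 borders found at day 14 were 84.4% with 800 kb, 85.5% with a rise of 0.4, 85.1% without balancing, and by construction 67.6% in the same bin and 89.4% within 2 bins. The plasma protein median at day 14 was 0.087 with 800 kb, 0.093 at full depth, 0.301 without balancing and 0.102 with unlisted pairs at 10, and its percentile ranged from 94.2 to 99.2. The fibroblast matrix local share at day 14 was -1.09 with 800 kb and -3.27 with another thinning. The slope rose by 0.13 at day 2 and 0.08 at day 4 between 400 and 800 kb. Inside-domain changes at full depth were -0.21, 3.7, 5.83 and 1.86 on days 2, 4, 6 and 14. Counting contacts of different bins alone put X at 0.83, 1.28 and 1.36 times day 0 on days 2, 4 and 14, and chromosome 15 at 1.09 on day 14. Reversed values were Apoa1 with 800 kb in insulation (-0.14), Dsg3 with 200 kb (-0.3) and Postn with 800 kb (1.3) in local share. Depth limits distant pairs: at matched depth, 65.0% of pairs 800 kb apart were listed at day 0 and 11.9% at 2000 kb.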

Other observations

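The genes in the next paragraph and the tests of the pattern after it were chosen once the values had been seen, except the test on listed contacts, which was written before its value was known.

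These genes lie outside the fixed lists, in bins with some of the largest changes in insulation score. Ces1b and Ces1c, neighbouring carboxylesterase genes on chromosome 8, rose by 0.99 and 0.95 at day 14, with 0.41 and 0.37 already at day 2. Ctso, in the bin next to Tdo2 on chromosome 3, rose by 0.97. Scores of these 2 bins share most of their contacts, so the gains at Ctso and Tdo2 are not separate changes. The highest gain of all was at Ccnh on chromosome 13, a partner of the kinase that activates cyclin-dependent kinases, with 0.34 at days 2 and 4, 0.86 at day 6 and 1.33 at day 14. Ptpn11, which encodes the phosphatase Shp2, went from -0.18 at day 2 to 1.06 at day 14. Adamts1, a matrix protease gene, was high from the start, with 0.94 at day 2 and 1.01 at day 14. The bin of Sds and Sdsl on chromosome 5, which encode serine dehydratase and its relative, was lower by -0.57 at day 6 and -0.72 at day 14, and that of the zinc finger gene Zfp648 on chromosome 1 by -0.43 at day 2 and -1.01 at day 14. Adgre1, which encodes the macrophage marker F4/80, was at -0.64 at day 14.

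Local share was lower at fibroblast matrix genes on all 4 days, and 3 explanations were tested. GC content is argued against, since the highest percentile among lists matched on GC was 0.2 over the days. A change in listed contacts under the count minimum is argued against by a highest percentile of 0.31 among lists matched on it. Cells of different origin cannot be told apart from a change over time: the list fell by 2.87 points at day 6 and 2.9 at day 2, when X stood near its day 0 level, but the stretch around Myc was then at 3.43 and 8.83, against 1.66 at day 0. A change in nearby contacts under the 3 factors may also account for it, as an untested hypothesis that rests on 1 day 0 map, and with a window of 800 kb the medians at days 4, 6 and 14 were -0.89, -0.19 and -1.09.

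Across 13902 gene bins, which are not independent replicates, the change in local share followed GC content, with r of -0.44 at day 2, -0.39 at day 4, -0.32 at day 6 and -0.17 at day 14. Changes in same-bin contacts had r of 0.75, 0.72, 0.63 and 0.67 with GC content across 58997 autosomal bins, and changes in insulation score -0.24 at day 6 and -0.05 at day 14 across 12908 gene bins. All of these share the day 0 map, so part of their likeness comes from it. Pairs 6 Mb or more apart with 50 or more contacts numbered 28 on chromosome 15 at day 2, 1 at day 6 and 27 at day 14, with 0 at days 0 and 4, against 4, 2 and 0 on all other chromosomes at days 2, 6 and 14.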
